A study of Mus musculus with 28 samples.

How the data were processed

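The series holds 28 Affymetrix oligonucleotide arrays of mouse retroperitoneal fat pads. Mice of the strain written C57BK/6J in the labels, 9 weeks old, ate a control diet or one with the trans-10 cis-12 isomer of conjugated linoleic acid (CLA) at 0.5%. Pads were taken on days 1, 2, 3, 4, 7, 10 and 17 of feeding. Each of the 14 groups of diet and day has 2 arrays. Per the labels, the pads of 10 mice were pooled, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 15 µg of total RNA. The labels do not settle whether the arrays of a group hold separate pools. Pools of 10 per group would come to 140 mice, the number the series record gives, and pools of 10 per array to 280. If the arrays of a group share a pool, the p-values of a day, of late minus early, of the interaction and of control by day measure technical spread only.

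The deposited values are log2 probe-set expression values made by the authors with RMA, which corrects background, normalises the arrays to each other by quantiles and summarises the probes of each set. The labels name RMA without a version, and the genome build behind the probe annotation is not stated. The values run from 1.90 to 14.18, and the array medians lie between 4.1 and 4.2. The values were used as deposited, with no filter on dim probe sets and no further normalisation.

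Of the 45101 probe sets, 34958 name 1 gene, 932 name several and 9211 have no gene name in the table of probes used here. These classes include 64 array controls, of which 13 name 1 gene and 51 do not, and 3 of the genes tested, Actb, Gapdh and Pcx, are represented by such a control. Of the probe sets that name 1 gene, 34754 matched the reference gene table (assembly GRCm38.p6) by gene ID. That table was used for names only and no coordinates are given. Each of the 18194 genes tested is represented by the probe set with the highest mean over the 28 arrays. More than 1 probe set was available for 9012 genes. The probe sets that name no single gene enter no comparison and are summarised apart, without the array controls.

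Differential expression was tested with limma 3.58.1 in R 4.3.3 with moderated variances. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. One model with the 14 groups as terms, 28 arrays and 14 residual degrees of freedom gave CLA minus control on each of the 7 days. The same model gave the F test of the diet by day interaction and the contrast of the mean CLA effect on days 7, 10 and 17 minus that on days 1, 2 and 3 (late minus early). It also gave the F test over the 7 control groups. The effect over all 7 days was tested on the means of the arrays of each group, with the day as a block and 6 residual degrees of freedom before moderation. The day is there the unit of replication, and differences between days count as spread. All tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg within a comparison, and genes with an adjusted p under 0.05 are called changed. Errors are standard errors of the model (SE). Every p-value below is an adjusted p from limma unless another test is named.

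Gene lists for 31 pathways, cell types and neighbouring tissues were written from textbook knowledge. They cover adipocyte identity, synthesis of fatty acids, triglycerides and cholesterol, lipolysis, fatty acid oxidation, brown and thermogenic adipocytes, oxidative phosphorylation and insulin signalling. They also cover macrophages, T cells, B and plasma cells, neutrophils, mast cells, endothelium, adipocyte progenitors, erythroid cells, cytokines and acute phase proteins, the interferon response and extracellular matrix. The remaining lists are the integrated stress and unfolded protein response, NRF2 and oxidative stress, cell cycle, apoptosis, immediate early genes, circadian clock, skeletal muscle, kidney, adrenal gland, mesothelium and exocrine pancreas. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists within a comparison. The test was repeated with the correlation estimated per list, and with fry, which tests whether a list's genes move one way on balance. Members past the threshold are counted over all genes tested and, beside that, adjusted over the list alone.

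The genes named were chosen by rule. Over all 7 days these are the 10 largest rises and 10 largest falls among changed genes with 1 direction on all days. For each day they are the 3 largest rises and 3 largest falls among changed genes whose CLA arrays both lay on the same side of both control arrays. For late minus early they are the 5 largest rises and falls. From each list they are the 4 changed members with the largest effect over all 7 days, or the 2 with the highest level where fewer than 2 changed. A fixed set of adipocyte, lipid, inflammation and stress genes was always taken. Of that set, Ucp2 and Cpt1b were not analysed here. Predicted genes without a name were left out of the choices by size. Other list members are named after their values were seen, where they moved against the rest of their list or show what moved in it.

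The comparisons, the lists, the rule for named genes and a first set of other settings were fixed before the data were examined. That set held another rule for the probe set of a gene, all probe sets, genes above the median level only, centring or quantile normalisation of the arrays, array weights, an intensity trend with a robust prior, a further minimum of a 2-fold change, a 2-fold change with no test, the 4 arrays of a day alone, replicate numbers as a block, other units of replication, other early days, and each array or day left out in turn. After the data were seen, 5 more settings were added. These leave out replicate 1 of control day 2, leave out the 4 replicate 1 arrays of days 1 and 2, use RNA quality as a covariate, take other control arrays for day 17, and take only days 7 and 10 as late. RNA quality was measured on each array as the mean 3' minus 5' difference of the control probe sets for actin and Gapdh, which grows as RNA is degraded or cRNA is short.

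The steps were tested on simulated data with 18194 genes, of which 200 were changed. At a simulated log2 change of 1, the test of day 7 recovered 76.5% of the changed genes, that over all 7 days 95%, late minus early 91.5%, control by day 73.5% and the interaction 1.5%. At a log2 change of 2 the shares were 99.5%, 99.5%, 98.5%, 98.5% and 95%. At a log2 change of 0.5 the share was 0% for each of the 5. These shares hold for 200 changed genes. Only the test over all 7 days was simulated with a spread between groups beyond that between arrays. The other shares assume that the arrays of a group show the whole spread, which the labels do not settle. In the data 7007 genes were called over all 7 days, which makes the adjusted threshold less strict, and changes below 0.5 passed there. With 2 arrays in a group, the number of arrays limits the precision of every daily value.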

Results

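Gene expression was measured in pooled retroperitoneal fat pads of mice after 1, 2, 3, 4, 7, 10 and 17 days on a diet with 0.5% trans-10 cis-12 CLA, a fatty acid isomer that lowers body fat in mice, or on the control diet. Each diet and day has 2 arrays, 28 in all, and no control array serves more than 1 day. The log2 signal ran from 1.90 to 14.18, and the correlation of the 2 arrays of a group across genes lay between 0.979 and 0.995. The number of arrays limits the precision of each daily value. The question put to the data is which transcripts of the fat pad change with CLA and when.

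Over all 7 days Mmp12, a macrophage elastase, had the largest rise of the genes named, by a log2 fold of 5.62 ± 0.81 (SE, n = 7 days, adjusted p = 0.000641). Other large rises were those of Rnf128, a ubiquitin ligase, at 5.15 ± 0.57, Rgs1, a regulator of G protein signalling in leukocytes, at 5.03 ± 0.55, Adam8, a metalloproteinase of myeloid cells, at 4.74 ± 0.47, and Ccl2, the chemokine that draws monocytes, at 4.12 ± 0.38. Timp4, a metalloproteinase inhibitor of fat, fell by 4.02 ± 0.42, Eci3, an enoyl-CoA isomerase, by 3.69 ± 0.31, Nnat, a small membrane protein, by 3.59 ± 0.31, and Elovl6, a fatty acid elongase, by 3.09 ± 0.21. Each of these 9 genes kept its direction on all 7 days, which the rule for naming them required.

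Of 18194 genes, 7007 changed over all 7 days, 3398 upward and 3609 downward. The other large rises were Atp6v0d2 (4.62), Il7r (4.37), Ptx3 (4.33), Gpnmb (4.28) and Clec4d (4.01), and the other large falls were Pon1 (-3.34), B3galt2 (-3.11), Acsm3 (-3.11), Mogat1 (-3.06), Amy1 (-2.98) and Chn1 (-2.97). The highest adjusted p among these 20 genes was 0.00133. A further probe set differed from the one used by a log2 fold of more than 1 for several of them, with 0.33 for Ptx3, 2.14 for Gpnmb, 2.99 for Il7r, -2.98 for Timp4, -0.23 for Elovl6 and -0.37 for Chn1.

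Genes that define adipocytes fell together. Of 25 measured genes of adipocyte identity, 24 fell and only Lpl did not pass (-0.13, adjusted p = 0.108), while all 25 fell when adjusted over the list alone. Slc2a4, the insulin-responsive glucose transporter, fell by 2.25 ± 0.12, Lep, the hormone leptin, by 1.87 ± 0.28, and the adipogenic transcription factors Cebpa and Pparg by 1.20 ± 0.14 and 1.12 ± 0.16. Adipoq, the hormone adiponectin, fell by 0.96 ± 0.05. The list median was -1.49, and this was the 1 list whose call over all 7 days held with the correlation estimated (adjusted p = 2.82e-13 at the preset correlation and adjusted p = 0.045 with an estimated correlation). Among the smaller falls, Cd36, a fatty acid transporter, fell by 0.27, and Fabp4, a fatty acid binding protein with a mean control level of 13.9, fell by 0.17 (adjusted p = 0.0393). The control levels of Fabp4 and Lpl (13.4) lay close to the highest value on any array, 14.18. Falls may be understated there, which was not tested. The call of Fabp4 was lost in 10 other settings, such as quantile normalisation (-0.10), and its further probe sets gave falls of up to -1.60. Lpl passed with its most variable probe set (-0.43), and the call of Cd36 was lost with replicate 1 of every group alone (-0.20).

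Lipid synthesis fell as well. Of 19 measured genes of fatty acid synthesis, 18 fell and 1, Fads2, did not pass, with the same counts when adjusted over the list alone. Pnpla3 fell by 2.72, Mlxipl, which encodes the carbohydrate response factor ChREBP, by 2.40, Srebf1, a lipogenic transcription factor, by 1.77, Fasn, the fatty acid synthase, by 1.60, and Scd1, the stearoyl-CoA desaturase, by 0.61, or by 1.76 with its other probe set. The list median was -1.62 (adjusted p = 7.12e-12, and adjusted p = 0.182 with an estimated correlation). Of 11 genes of triglyceride synthesis, 9 fell, or 10 adjusted over the list alone, among them Pck1 (-2.42, a further probe set at 0.06), which feeds glycerol synthesis, Lpin1 (-1.74) and Dgat2 (-1.37), with a median of -0.96 (adjusted p = 1.24e-05, and adjusted p = 0.274 with an estimated correlation). Of 9 genes of lipolysis, 8 fell, or 9 adjusted over the list alone, with a median of -1.06 (adjusted p = 9.38e-06, and adjusted p = 0.17 with an estimated correlation). They include the lipases Lipe (-2.04, or -0.07 with its other probe set) and Pnpla2 (-1.54), which release fatty acids, and also Pde3b (-1.53) and G0s2 (-1.06), which restrain lipolysis. Of 18 genes of cholesterol synthesis, 10 fell in both counts, such as Fdft1 (-1.59), the squalene synthase, and Pmvk (-1.36), with a median of -0.58 (adjusted p = 0.00279, and adjusted p = 0.616 with an estimated correlation). Of 16 genes of insulin signalling, 12 fell, or 13 adjusted over the list alone, where 1, Grb10, rose (0.26), with a median of -1.30 (adjusted p = 9.02e-07, and adjusted p = 0.184 with an estimated correlation). Gys2, a glycogen synthase, fell by 2.21 and the adaptor Irs3 by 1.85.

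Genes of fatty acid oxidation and of oxidative phosphorylation were lower on average. Of 22 measured genes of fatty acid oxidation, 14 fell and 3 rose in both counts, with a median of -0.52 (adjusted p = 0.00046, and adjusted p = 0.527 with an estimated correlation). Ehhadh fell by 1.73 and Eci1 by 1.27, whereas Cpt1a, which admits fatty acids to mitochondria, rose by 0.92 and the thioesterases Acot1 and Acot2 rose by 0.88 and 0.52. Of 31 genes of oxidative phosphorylation, 27 fell, or 28 adjusted over the list alone, such as Sdha (-0.86) and Ndufs1 (-0.70), with a median of -0.42 (adjusted p = 5e-09, and adjusted p = 0.379 with an estimated correlation). Of 15 genes of brown and thermogenic adipocytes, 5 fell and 1, Elovl3, rose (1.20) in both counts, with no shift of the list called (median -0.10, adjusted p = 0.393). Ucp3 fell by 2.04 and Cidea by 2.27, a call that was lost without day 2 (-1.92), day 3 (-1.89) or day 4 (-2.0). Ucp1, the uncoupling protein of brown fat, and Ppargc1a, a transcriptional coactivator, did not pass over all days, at 1.22 ± 0.93 (adjusted p = 0.354) and -0.46 (adjusted p = 0.11), and their daily values had both signs. Ucp1 passed with the 28 arrays as the unit, and Ppargc1a did so without day 7 (-0.61).

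Macrophage genes rose. Of 26 measured, 25 rose and 1, Cd163, did not pass, while it fell when adjusted over the list alone. Gpnmb rose by 4.28, Fcgr1, an Fc receptor, by 3.47, Trem2, a lipid receptor, by 3.04 with a further probe set at 0.07, Cd68, a lysosomal glycoprotein, by 2.78, and Adgre1, a macrophage surface receptor, by 2.35. The list median was 2.14 (adjusted p = 4.97e-12, and adjusted p = 0.3 with an estimated correlation). Of 27 cytokine and acute phase genes, 22 rose and 1, Orm1, fell (-2.01), with 23 and 1 adjusted over the list alone. Il1rn, the interleukin 1 receptor antagonist, rose by 3.94, Ccl7 by 3.28, Saa3, an acute phase protein, by 1.92 and Tnf by 0.45, and Il6 did not pass at 0.87 (adjusted p = 0.186), though it did without day 1 at 0.31. The list median was 1.28 (adjusted p = 1.59e-10, and adjusted p = 0.17 with an estimated correlation). Of 16 interferon response genes, 12 rose, such as Cxcl10 (2.56) and Oas1a (1.90), and 1, the chemokine Cxcl9, fell (-0.48) in both counts, with a median of 0.77 (adjusted p = 5.66e-05, and adjusted p = 0.3 with an estimated correlation).

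Lists of other leukocytes were not called. Among 12 T cell genes the 1 riser was Il7r (4.37), a receptor also found outside T cells, and the 2 that fell, Zap70 (-0.23) and Cd6 (-0.20), no longer passed without replicate 1 of every group. This list's median was -0.11 and its mean 0.27, and its test pointed down (adjusted p = 0.598). Among 13 B and plasma cell genes 3 rose, Blnk (3.01) and Cd22 (1.07), both signalling proteins, and Cd79b (0.46, lost without day 3 at 0.42), while the median was -0.15, the mean 0.24 and the test pointed down (adjusted p = 0.871). Counts adjusted over the list alone were the same for both. Among 11 neutrophil genes Csf3r (0.73) and Mmp8 (0.38) rose and Elane fell (-0.23), and 1 rose and 0 fell adjusted over the list alone. This list had a median of -0.02, a mean of 0.16 and a test that pointed up (adjusted p = 0.598). The calls of Mmp8 and Elane were lost with either replicate number left out. Among 9 mast cell genes 1, Fcer1a, rose (0.66), and 0 did in limma's test adjusted over the list alone (3 at an unadjusted p under 0.05), with a median of 0.15 (adjusted p = 0.194).

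Cell cycle, immediate early and stress response genes rose. Of 26 cell cycle genes, 25 rose, or 26 adjusted over the list alone, among them the proliferation marker Mki67 (2.84 ± 0.42), the ribonucleotide reductase subunit Rrm2 (3.13) and Top2a (2.77, with a further probe set at -0.04), and the median was 1.91 (adjusted p = 1.59e-10, and adjusted p = 0.379 with an estimated correlation). Of 14 immediate early genes, 13 rose in both counts, led by the transcription factors Fos (3.70) and Egr2 (3.29), with a median of 1.45 (adjusted p = 8.98e-09, and adjusted p = 0.182 with an estimated correlation). Of 27 genes of the integrated stress and unfolded protein response, 17 rose and 6 fell in both counts, with a median of 0.63 (adjusted p = 0.000497, and adjusted p = 0.449 with an estimated correlation). The risers include the stress transcription factors Atf3 (3.94) and Ddit3 (1.77, a further probe set at 0.25), the pseudokinase Trib3 (2.17) and the chaperone Hspa5 (1.18), and the fallers include Phgdh (-1.78), Psat1 (-0.42) and Asns (-0.76), enzymes of serine and asparagine synthesis. Of 19 NRF2 and oxidative stress genes, 10 rose, such as Hmox1 (2.95), the haem oxygenase, and Srxn1 (2.23), and 5 fell, such as the glutathione transferases Gsta3 (-2.13) and Gsta4 (-1.66), in both counts, and the list was not called (median 0.34, adjusted p = 0.208). Of 16 apoptosis genes, 10 rose and 1 fell, or 11 and 2 adjusted over the list alone, with a median of 0.54 (adjusted p = 0.000449, and adjusted p = 0.11 with an estimated correlation). Bcl2l11 (2.04) and Pmaip1 (1.66), which promote cell death, rose, as did Birc3 (0.92) and Bcl2l1 (0.46), which oppose it, and the faller was Bcl2 (-0.53). Of 15 circadian clock genes, 7 fell and 1 rose, Per1 (0.26), or 8 and 1 adjusted over the list alone, with Nr1d1 (-1.54), a repressor of the clock, the largest. That list had a median of -0.24 and was not called by camera (adjusted p = 0.107) but was by fry (adjusted p = 0.000665).

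Matrix genes rose and endothelial genes fell. Of 30 extracellular matrix genes, 17 rose and 1 fell, or 19 and 3 adjusted over the list alone, with a median of 0.57 (adjusted p = 8.2e-06, and adjusted p = 0.379 with an estimated correlation). Proteases and their inhibitor led, with Mmp12 at 5.62, Timp1 at 3.16 ± 0.13, Mmp13 at 2.07 and Mmp3 at 1.77, the collagen Col1a1 rose by 0.59, and the basement membrane collagen Col4a2 fell by 0.26. Of 13 endothelial genes, 8 fell in both counts, among them Cdh5 (-1.26) and the receptor Kdr (-1.21), with a median of -0.78 (adjusted p = 0.00147, and adjusted p = 0.449 with an estimated correlation). Of 13 adipocyte progenitor genes, 5 fell in both counts, with Zfp423 (-1.29), a regulator of fat cell commitment, the largest, and the list was not called (median -0.18, adjusted p = 0.537). The other 4 were Pi16 (-0.43), Fgf10 (-0.36), Ccn5 (-0.30) and Gata2 (-0.27). The first 3 lost their calls when replicate 1 of every group was used alone, at -0.35, -0.21 and -0.19, and Gata2 was not followed in other settings.

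Markers of tissues next to the fat pad were measured beside these groups. Of 11 mesothelial genes, 6 fell in both counts, such as Upk3b (-0.62) and Msln (-0.49), with a median of -0.38 (adjusted p = 0.0191, and adjusted p = 0.53 with an estimated correlation). Of 15 skeletal muscle genes, 3 fell in both counts, Myl1 (-0.87), Myh1 (-0.74) and Mb (-0.45), and the list median was -0.56 (adjusted p = 0.0329, and adjusted p = 0.726 with an estimated correlation). The muscle call was lost without day 3 (adjusted p = 0.0848), day 4 (adjusted p = 0.0917), day 7 (adjusted p = 0.105) or day 17 (adjusted p = 0.0547) and by fry (adjusted p = 0.137), and those of the 3 genes were lost with no day block. Of 11 adrenal genes, Star (1.18), which carries cholesterol into mitochondria, rose and Mc2r (-2.52), the corticotropin receptor that fat cells also carry, and Dbh (-0.27) fell in both counts (median -0.03, adjusted p = 0.796). Dbh was not called with replicate 1 of every group alone (-0.21). In 12 kidney genes (median -0.04, adjusted p = 0.828) and 9 genes of the exocrine pancreas, 0 passed in limma, and 1 of each list had an unadjusted p under 0.05. The pancreas list had a median of 0.005, a mean of -0.0092 and a test that pointed up (adjusted p = 0.871). Of 4 erythroid genes, Alas2, the first enzyme of haem synthesis in red cells, fell by 0.72, and 0 fell adjusted over the list alone (1 at an unadjusted p under 0.05). Its call was lost without day 4, 7, 10 or 17, with values between -0.69 and -0.55, and the list had a median of 0.02, a mean of -0.14 and a test that pointed up (adjusted p = 0.982).

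**Figure D1:**
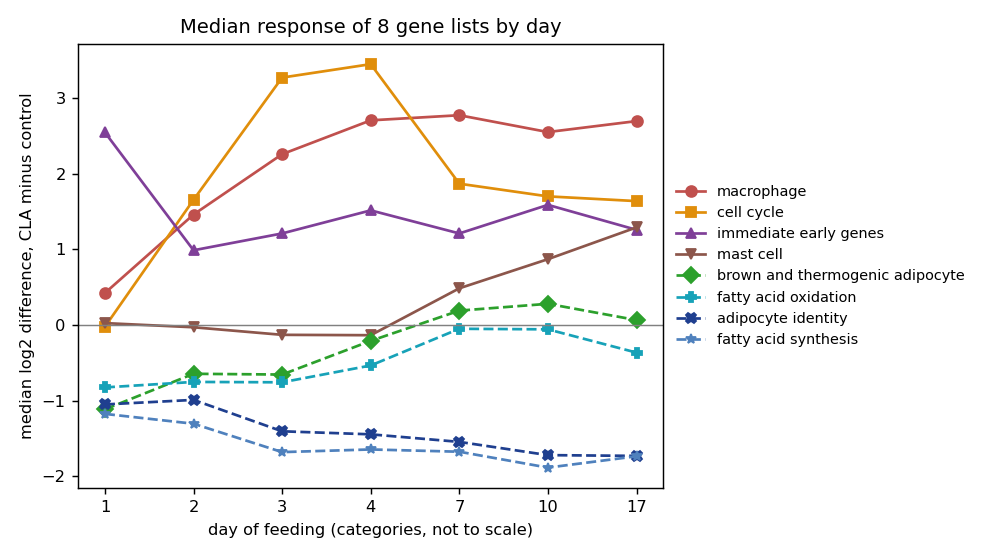
Median log2 difference of CLA minus control (vertical axis) on each day of feeding (horizontal axis) over the measured genes of 8 lists, 1 line per list. Macrophage genes reached 2.77 on day 7, cell cycle genes 3.45 on day 4, and genes of fatty acid synthesis lay between -1.89 and -1.18 on every day.

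On day 1 immediate early, cytokine and stress response genes rose. Ptx3, a pentraxin of innate immunity, rose by 6.29 ± 0.45 (SE, n = 2 arrays per diet, adjusted p = 2.22e-08 in limma), Hspa1a, a heat shock protein, by 5.85 ± 0.27 and Ccl2 by 5.62 ± 0.73. Il6 rose by 4.21 ± 0.25 and passed on no other of the 7 days (interaction adjusted p = 3.79e-06). The largest falls were those of B3galt2, a galactosyltransferase, by 3.90 ± 0.35, and of the hormone receptors Mc2r, by 3.62 ± 0.21, and Oxtr, by 3.20 ± 0.31. The day had 3420 changed genes, 1449 up and 1971 down, or 1895 up and 1708 down with each array centred on its median. Of 14 immediate early genes 13 rose (median 2.55, adjusted p = 2.41e-14), of 27 cytokine and acute phase genes 23 rose and 1 fell (1.69, adjusted p = 5.11e-17), and of 27 stress response genes 17 rose and 2 fell (1.29, adjusted p = 1.32e-11), all 3 with adjusted p = 0.019 with an estimated correlation. Adjusted over the list alone these were 13 up, 24 up and 1 down, and 19 up and 3 down. Of 15 brown and thermogenic genes 10 fell in both counts, Ucp1 by 2.13 (list median -1.12, adjusted p = 2.35e-06, and adjusted p = 0.019 with an estimated correlation). Of 26 macrophage genes 6 rose, or 8 with 1 fall adjusted over the list alone, and the median was 0.42 (adjusted p = 0.0051, and adjusted p = 0.593 with an estimated correlation). Without replicate 1 of control day 2, which enters the pooled spread, 10 macrophage genes rose and 1 fell on this day (adjusted p = 8.02e-05). In the cell cycle list 0 of 26 passed in limma (median -0.02, adjusted p = 0.953), with 2 at an unadjusted p under 0.05, and 1 fell without that array.

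RNA quality differed on this day. The 3' minus 5' difference was 2.02 and 1.78 in the CLA arrays and 2.05 and 0.83 in the control arrays, against 0.595 to 1.32 in the CLA and 0.625 to 1.46 in the control arrays of the later days. Of the day's genes, 1085 were called on no other day. Their median change against the control array of like quality was 92.2% of that against the other control array, with 0.72 against 0.89 for the 601 that rose and -0.82 against -0.77 for the 484 that fell. The count was 1779 with array weights and 591 with the 4 arrays of the day alone.

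On day 2 macrophage and cell cycle genes rose. Chil3, a chitinase-like protein of macrophages, rose by 3.70 ± 1.05 (SE, n = 2 arrays per diet, adjusted p = 0.0282 in limma), Rgs1 by 3.38 ± 0.63 and Rnf128 by 3.35 ± 0.66. Cidea, a lipid droplet protein, fell by 4.33 ± 0.41, Eci3 by 3.58 ± 0.21 and Nnat by 3.30 ± 0.58. Of 26 cell cycle genes 25 rose in both counts, Mki67 by 2.20 (median 1.66, adjusted p = 1e-26, and adjusted p = 0.0333 with an estimated correlation). Of 26 macrophage genes 18 rose, or 23 with 1 fall adjusted over the list alone (median 1.46, adjusted p = 5.68e-17, and adjusted p = 0.0463 with an estimated correlation). Of 31 oxidative phosphorylation genes 19 fell, or 25 adjusted over the list alone (median -0.63, adjusted p = 1.01e-16, and adjusted p = 0.0247 with an estimated correlation).

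The day's 1852 changed genes, 881 up and 971 down, depend on single arrays. Replicate 1 of the control group lay between the other control and the CLA arrays, with Mmp12 at 8.28 against 3.87 in its partner. Without it 2434 genes changed, 1367 up and 1067 down, Mmp12 rose by 5.48, Chil3 by 6.67, Rgs1 by 5.15, Rnf128 by 5.195 and Mki67 by 3.45, and the medians of the macrophage and cell cycle lists were 1.93 and 2.42, while 12 of the 31 oxidative phosphorylation genes fell (median -0.65). Without replicate 2 of the control group 343 genes changed, and Chil3 (0.72), Mmp12 (1.07), Mki67 (0.96) and Nnat (-2.29) were not called, while Rgs1 rose by 1.61 and Rnf128 by 1.495. In that setting 2 macrophage and 4 cell cycle genes rose (medians 0.70 and 0.97) and 5 oxidative phosphorylation genes fell (median -0.60). Chil3 was not called without either CLA array of the day (3.36 and 4.04) or with a robust prior either. Without replicate 2 of the CLA group 884 genes changed. The 4 arrays of the day alone gave 0 genes in limma, with 2412 at an unadjusted p under 0.05, and the replicate block within days gave 3037.

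On day 3 Rnf128 rose by 6.34 ± 0.66 (SE, n = 2 arrays per diet, adjusted p = 1.24e-06 in limma), Rgs1 by 6.29 ± 0.63 and Adam8 by 6.03 ± 0.64, while Cidea fell by 4.51 ± 0.41, Nnat by 4.39 ± 0.58 and Timp4 by 4.14 ± 0.33. On day 4 Mmp12 rose by 6.98 ± 0.77, Rnf128 by 6.68 ± 0.66 and Il1rn by 6.20 ± 0.55, while Nnat fell by 5.02 ± 0.58, Timp4 by 4.65 ± 0.33 and Eci3 by 3.97 ± 0.21. Of 26 cell cycle genes 25 rose on each day in both counts, with medians of 3.27 on day 3 (adjusted p = 1.22e-30, and adjusted p = 0.0439 with an estimated correlation) and 3.45 on day 4 (adjusted p = 1.23e-29, and adjusted p = 0.0593 with an estimated correlation). Of 13 endothelial genes 9 fell on day 4 in both counts (median -1.20, adjusted p = 5.07e-05, and adjusted p = 0.154 with an estimated correlation), and 6 of 11 mesothelial genes fell beside them (median -0.82, adjusted p = 0.00133, and adjusted p = 0.157 with an estimated correlation). Of all genes 4056 changed on day 3, 2048 up and 2008 down, and 4379 on day 4, 2328 up and 2051 down. Without replicate 2 of control day 3 the count of day 3 was 2687, and without replicate 2 of CLA day 4 that of day 4 was 2846.

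**Figure D2:**
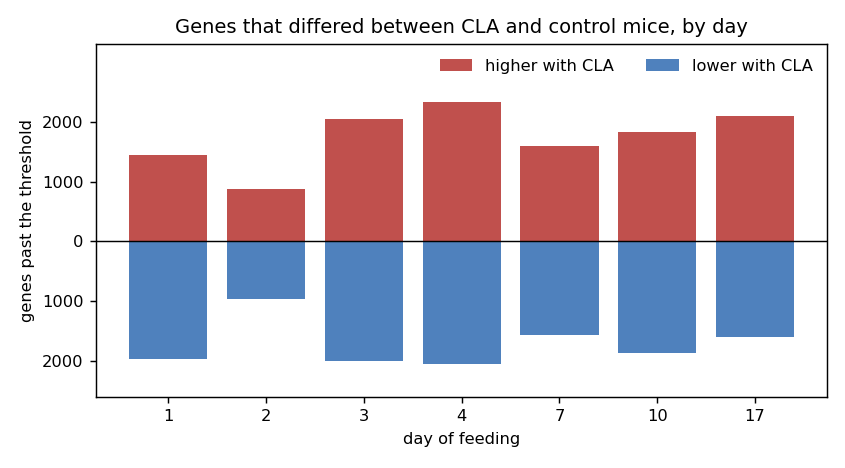
Number of genes called changed by limma (vertical axis) on each day of feeding (horizontal axis), with bars for genes up and genes down with CLA. The counts run from 881 up and 971 down on day 2 to 2328 up and 2051 down on day 4.

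Macrophage genes and Ucp1 were among the rises of days 7 and 10. Mmp12 rose by 7.34 ± 0.77 on day 7 (SE, n = 2 arrays per diet, adjusted p = 1.57e-06 in limma) and by 7.57 ± 0.77 on day 10, Atp6v0d2, a subunit of the lysosomal proton pump, by 6.57 ± 0.38 and 6.19 ± 0.38, Gpnmb by 6.02 ± 0.34 on day 7 and Rnf128 by 6.31 ± 0.66 on day 10. Timp4 fell by 5.25 ± 0.33 and 5.22 ± 0.33, Pon1, a paraoxonase, by 4.12 ± 0.65 and 4.45 ± 0.65, and Eci3 by 3.94 ± 0.21 and 4.32 ± 0.21. Ucp1 rose by 4.34 ± 0.57 on day 7 and 4.70 ± 0.57 on day 10. On day 7, 24 of 26 macrophage genes rose in both counts (median 2.77, adjusted p = 2.11e-29, and adjusted p = 0.0425 with an estimated correlation). On day 10, 20 of 30 matrix genes rose, or 22 adjusted over the list alone (median 1.13, adjusted p = 4.22e-14, and adjusted p = 0.0412 with an estimated correlation), and 6 of 15 brown and thermogenic genes rose and 2 fell in both counts (median 0.28, adjusted p = 0.00358, and adjusted p = 0.103 with an estimated correlation). On day 7, 4 genes of that list rose, or 5 adjusted over the list alone, and 1 fell (median 0.19, adjusted p = 0.0447, and adjusted p = 0.261 with an estimated correlation), a call lost without replicate 1 of control day 2 (adjusted p = 0.068). Day 7 had 3151 changed genes, 1591 up and 1560 down, and day 10 had 3687, 1825 up and 1862 down. Without replicate 1 of CLA day 7 the first count was 2095, and without replicate 1 of CLA day 10 the second was 2432.

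On day 17 the macrophage genes rose and genes of cholesterol synthesis fell. Mmp12 rose by 7.58 ± 0.77 (SE, n = 2 arrays per diet, adjusted p = 9.64e-07 in limma), Rgs1 by 6.31 ± 0.63 and Atp6v0d2 by 6.03 ± 0.38, while Eci3 fell by 4.84 ± 0.21, Timp4 by 4.55 ± 0.33 and Mogat1, an acyltransferase of triglyceride synthesis, by 4.48 ± 0.25. Of 26 macrophage genes 25 rose in both counts (median 2.70, adjusted p = 1.92e-27, and adjusted p = 0.027 with an estimated correlation). Of 18 cholesterol synthesis genes 12 fell, or 13 adjusted over the list alone, Fdft1 by 2.22 (median -1.32, adjusted p = 9.13e-10, and adjusted p = 0.027 with an estimated correlation), and all 19 fatty acid synthesis genes fell in both counts (median -1.74, adjusted p = 4.23e-20, and adjusted p = 0.027 with an estimated correlation). Of 9 mast cell genes 5 rose, or 6 adjusted over the list alone, the protease Cpa3 by 2.39 (median 1.29, adjusted p = 0.000109, and adjusted p = 0.0525 with an estimated correlation). The day had 3688 changed genes, 2090 up and 1598 down, and 2352 without replicate 1 of its CLA group. With each array centred on its median, which moved the median of all genes by -0.105, 1780 rose and 2313 fell. Liver transcripts were high in the control arrays of this day, with Alb, the albumin gene, at 10.93 and 9.31. In the CLA arrays of the day Alb was at 6.74 and 8.81. Of 26 measured hepatocyte markers 15 fell with CLA on this day. Not every such fall goes with high controls, as Cyp2e1 was at 13.12 in them, 13.00 in the other controls and 10.10 with CLA. With the control arrays of days 4, 7 and 10 in place of this day's, 4469 genes changed, 3356 of them shared.

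Genes called on 1 day were often called on others. On all 7 days 164 genes rose and 450 fell, while 276 rose on at least 1 day and fell on another. Days 3 and 4 shared 1759 risers against 262 for independent days, and days 1 and 2 shared 278 against 70.2. The 1211 genes that rose at least 2-fold on day 17 had medians of 0.24, 0.81, 1.38, 1.57, 1.39, 1.44 and 1.55 on the successive days. The 742 that fell at least 2-fold had -1.07, -0.93, -1.33, -1.43, -1.34, -1.40 and -1.45. Both sets were chosen on day 17, so their values on that day are not independent evidence.

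Ucp1 had the largest difference between the effect of CLA on days 7, 10 and 17 and that on days 1, 2 and 3. The late minus early difference was 5.79 ± 0.46 for Ucp1 (SE, 12 arrays late and 12 early, or 6 pools each if the arrays of a group share a pool, adjusted p = 2.49e-07), 4.20 ± 0.63 for Mmp12, 4.03 ± 0.37 for Fabp3, a fatty acid binding protein of oxidative tissue whose other probe set gave -0.14 over all days, 3.88 ± 0.30 for Gpr34, a lysophosphatidylserine receptor, and 3.75 ± 0.33 for Cidea. Ucp1 was at -2.13 on day 1 and at 4.34, 4.70 and 3.86 on the late days, and Cidea went from -4.51 on day 3 to 0.28 on day 10. In the opposite direction were Chil3 (-3.96 ± 0.85), the neutrophil gene S100a9 (-2.33 ± 0.72, adjusted p = 0.0471), the epithelial proteins Sprr1a (-2.27 ± 0.56) and Cdsn (-2.17 ± 0.49), and Timp4 (-2.17 ± 0.27). Replicate 1 of control day 2, which lay between the diets, enters the early effect. Without it the day 2 effect was 5.475 for Mmp12 and 6.67 for Chil3, against 3.27 and 3.695 with it. That array thus makes the difference larger for Mmp12 and smaller in size for Chil3. In all, 1767 genes differed, 1128 upward and 639 downward, or 942 and 1069 with each array centred on its median, and the F test of the interaction called 1786.

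By list, 9 of 15 brown and thermogenic genes had a higher late effect, or 12 adjusted over the list alone (median 1.15, adjusted p = 1.56e-13, and adjusted p = 0.00331 with an estimated correlation). The list's medians were -1.12, -0.65 and -0.66 on days 1, 2 and 3 and 0.19, 0.28 and 0.07 on days 7, 10 and 17, so its early falls exceeded its late rises, and the list was not called on day 17 (adjusted p = 0.869). A higher late effect was also found for 19 of 26 macrophage genes, or 21 over the list alone, with Gpnmb at 3.43 and Adgre1 at 2.04 (median 1.21, adjusted p = 7.14e-22, and adjusted p = 0.0363 with an estimated correlation). Without replicate 1 of control day 2 the day 2 median of the macrophage list was higher, at 1.93, so that array adds to this difference. Higher late effects were also found for 8 of 22 fatty acid oxidation genes, or 16 over the list alone (median 0.56, adjusted p = 1.04e-09, and adjusted p = 0.0287 with an estimated correlation), and for 6 of 9 mast cell genes in both counts, with Cpa3 at 1.72 and Cma1 at 1.71 (median 1.11, adjusted p = 2.08e-06, and adjusted p = 0.0325 with an estimated correlation). For 14 of 30 matrix genes the late effect was higher, or for 18 with 1 lower over the list alone, among them Mmp2 at 1.65 and Lum at 1.71 (median 0.57, adjusted p = 3.88e-10, and adjusted p = 0.0451 with an estimated correlation). For oxidative phosphorylation the counts were 9 of 31, or 12 over the list alone (median 0.31, adjusted p = 3.84e-09, and adjusted p = 0.0818 with an estimated correlation). The medians of both oxidation lists stayed negative on days 7, 10 and 17. They were -0.05, -0.0575 and -0.365 for fatty acid oxidation and -0.205, -0.28 and -0.255 for oxidative phosphorylation. By these medians the higher late effect was a smaller fall and not a rise. Lower late effects were found for 7 of 18 cholesterol synthesis genes, or 9 over the list alone, with Sqle at -1.39 (median -0.57, adjusted p = 1.23e-07, and adjusted p = 0.0403 with an estimated correlation). For fatty acid synthesis 6 of 19 were lower and 1, Thrsp, higher (0.81), or 10 and 1 over the list alone (median -0.45, adjusted p = 0.00013, and adjusted p = 0.289 with an estimated correlation), and 5 of 19 NRF2 genes were lower in both counts, Gsta3 (-1.06), Gsta4 (-1.17), Mt2 (-0.85), Slc7a11 (-0.77) and Gstp1 (-0.56), of which the 2 glutathione transferases named first had fallen over all days (median -0.39, adjusted p = 0.000421, and adjusted p = 0.0977 with an estimated correlation).

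With the 6 daily differences as the unit 98 genes differed, and Mmp12 (adjusted p = 0.139), Timp4 (adjusted p = 0.151), Cdsn (adjusted p = 0.0986), Sprr1a (adjusted p = 0.191) and S100a9 (adjusted p = 0.193) were not called. S100a9 lost its call in 23 settings in all, among them array weights, and Sprr1a lost it with days 7 and 10 only as late (-2.04), a setting with 1178 genes in all. The replicate block within days gave 3046 genes for this difference and 3254 for the interaction.

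**Figure D3:**
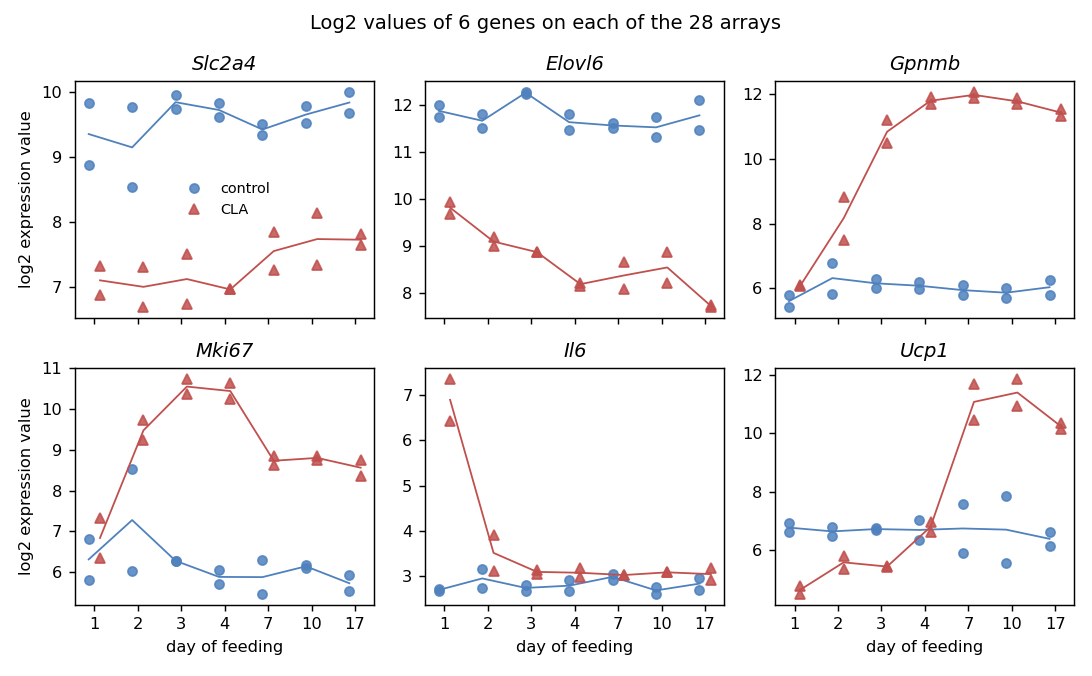
Log2 expression (vertical axis) of Slc2a4, Elovl6, Gpnmb, Mki67, Il6 and Ucp1 on each of the 28 arrays by day of feeding (horizontal axis), with circles for control, triangles for CLA and lines through the means of the 2 arrays of a group. Il6 was high with CLA on day 1 (difference 4.21), and Ucp1 on days 7, 10 and 17 (differences 4.34, 4.70 and 3.86).

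Between the control groups of the 7 days few genes differed, and most of them encode liver proteins. Fabp1, the liver fatty acid binding protein, stood at 7.93 in the controls of day 17 and between 2.82 and 4.22 in those of the other days (adjusted p = 0.00138). Serpina1c, an antitrypsin, stood at 9.19 and the apolipoprotein gene Apoa2 at 8.46 on day 17. The test called 21 genes, of which 20 were highest on day 17 and 1, Adcy10, on day 3, and 19 of the 21 fell with CLA on day 17. At an unadjusted p under 0.05 there were 1069. Among genes above the median level 0 were called in limma, with 389 at an unadjusted p under 0.05. The count was 225 without replicate 2 of control day 2, 37 without replicate 2 of control day 7, 36 without replicate 2 of control day 17 and 36 with the replicate block. Without replicate 1 of control day 17 it was 31, of which 5 were among the 21, and without replicate 2 of that group 16 were. Fabp1 was called in both cases, and Serpina1c and Apoa2 in neither.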

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

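The tests of the array between the diets, the hepatocyte markers and the macrophage markers were chosen only after those results were seen, while the kidney and pancreas comparison and the exchanges of diets and days were set beforehand.

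Replicate 1 of control day 2 lay between the CLA and control arrays. On the linear scale its median fraction of the way from the control to the CLA level was 0.437 in 235 genes that rise with CLA on days 3 to 17 and 0.432 in 122 that fall, a difference of 0.00559 (95% bootstrap interval -0.0527 to 0.0341 over genes, which are not independent). Equal fractions are what a mixture of RNA or tissue of CLA mice into this sample would give, and that is a candidate explanation. A uniformly weaker response in every cell needs equal shares on the log2 scale, where these differed by 0.372 (0.329 to 0.418). An uneven partial response is not excluded by this. The CLA arrays of day 1 also had unequal shares, in the opposite order, at 0.240 and 0.251 in rising and 0.862 and 0.833 in falling genes. Exchanged labels need a share near 1, against 0.652 in rising genes with no CLA array of the day near the controls. RNA quality is argued against by 2 other control arrays with as large a 3' minus 5' difference, whose shares were at most 0.0733.

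Liver transcripts were high in the control arrays of day 17. Of 26 measured hepatocyte markers, a list without the genes in which the pattern was found, 17 were higher in both of these arrays than in each of 12 other control arrays, against 1.36% of all genes, and their median shift was 1.30 (0.49 to 1.48). Liver RNA in these samples may be the source: Alb reached 10.93 and 9.31 and Ttr 8.27 and 6.61, the median shift was 1.71 and 0.76 in the arrays, and 0.42 and -0.02 in the CLA arrays of the day. The kidney and pancreas lists, with medians of 0.07 and 0.0883 and 0 genes above all other controls in each, argue against RNA of those organs. Of the hepatocyte markers 2 had a mean level over 7 in the other control arrays, Cyp2e1 and Apoc1, and a change of the fat itself with feeding time stays open and was not tested.

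Macrophage markers rose while adipocyte genes fell. A lower share of adipocyte RNA alone would raise every other cell type alike, but the medians were 2.14 for macrophages, -0.18 for progenitors, -0.38 for mesothelium and -0.78 for endothelium, and the smallest gap was 2.32 (1.54 to 2.61). All 8 general markers rose, but they belong to the list already seen to rise, and more macrophages or a higher level per macrophage could each raise them. The rises were unequal, from Csf1r (0.75 ± 0.20) and Laptm5 (1.81 ± 0.24) to Mpeg1 (3.00 ± 0.35). More macrophages in an unchanged state would raise all 8 alike, so number alone does not account for these sizes. How far number and level per cell each contributed cannot be told apart in pooled tissue without cell counts.

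Chance was weighed by exchanging the diets within days. For the genes changed over all 7 days, 1 of the 64 exchanges, the real one, gave as many as 7007. The highest of the others, with 2924, had the 6 days after day 1 exchanged. That equals an exchange of day 1 alone, so it kept most of the real diets, and every other exchange gave 0 genes in limma. A share of 1 in 64 is the smallest these exchanges can give, so it argues against chance without excluding it. For the lists, 10 of the 64 gave as many as the real 19, and the highest other gave 22. All of the others with as many had only 1 or 2 days exchanged, so they kept most of the real diets. The exchanges therefore cannot decide about chance for that count, and it cannot be excluded. For late minus early, the 10 splits of the 6 days are too few for such a share, and 1 split gave as many as the real 1767, with 718 the highest of the others.

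The effect of CLA differed between days by the test of the difference for 1786 genes over the 7 days and for 1767 between late and early days. Late minus early, the genes with the largest differences were Ucp1 (5.79), Mmp12 (4.20), Fabp3 (4.03), Gpr34 (3.88), Cidea (3.75), Chil3 (-3.96), S100a9 (-2.33), Sprr1a (-2.27), Timp4 (-2.17) and Cdsn (-2.17). The lists with a difference had medians of 1.15 (brown and thermogenic adipocyte), 1.21 (macrophage), 1.11 (mast cell), 0.57 (extracellular matrix), 0.56 (fatty acid oxidation), 0.31 (oxidative phosphorylation), -0.39 (NRF2), -0.45 (fatty acid synthesis) and -0.57 (cholesterol synthesis). Of these calls, 3 were lost with the correlation estimated, those of oxidative phosphorylation (adjusted p = 0.0818 with an estimated correlation), NRF2 (adjusted p = 0.0977) and fatty acid synthesis (adjusted p = 0.289). Of 10092 probe sets that name no single gene and enter no comparison, 1735 changed over all 7 days in limma, 818 up and 917 down, or 17.2% against 34.1% of those that name 1 gene.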

How the results depend on the processing

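The settings without control day 2 replicate 1 in the other days' counts, without the 4 replicate 1 arrays of days 1 and 2, with the 3' minus 5' covariate, with other controls for day 17 and with days 7 and 10 as late were chosen after the data were seen. No list or named gene with a call reversed in any setting run, but the direction that held more of the changed genes did. Counts stayed within 1.5 times in 214 of 256 settings of 11 results. Calls stayed on their side of the threshold in 348 of 372 settings of 31 lists (23 lost, 1 gained) and in 3566 of 3693 settings of 193 results of named genes (116 lost, 11 gained). The estimated correlation ended the calls of 18 lists, all but that of adipocyte identity.

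The larger of the counts up and down turned over in 36 of 192 settings, and in at least 1 for each day, over all 7 days and for late minus early, so neither direction is read as the larger. With each array centred on its median there were 1895 up and 1708 down on day 1, 1946 and 2165 on day 3, 2180 and 2270 on day 4, 1520 and 1704 on day 7, 1780 and 2313 on day 17, and 942 and 1069 for late minus early. Quantile normalisation gave 2011 and 2118 on day 3, 2138 and 2343 on day 4, 1582 and 1695 on day 7, and 1878 and 1923 on day 17. Without replicate 1 of control day 4 that day had 1566 up and 1731 down. Centring moved the median change of all genes by -0.105 on day 17, 0.0725 on day 1 and -0.0683 for late minus early, and by less elsewhere.

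By construction, requiring a 2-fold change lowered the counts to 1565, 965, 2106, 2319, 1784, 1855 and 1953 on the successive days, 1620 over all days and 547 for late minus early. A 2-fold change with no test gave 1633, 1073, 2197, 2387, 1876, 1916 and 2058. All probe sets, a larger number of tests, gave 5482, 6628, 6935, 4925, 5654 and 5692 on days 1, 3, 4, 7, 10 and 17 and 13635 over all days. The 4 arrays of a day alone gave 591 genes on day 1 and 0 on day 2 in limma (2412 at an unadjusted p under 0.05), but 4320, 5512, 3179, 3286 and 5119 on days 3, 4, 7, 10 and 17. The 6 daily differences as the unit gave 98 for late minus early. Array weights gave 1779 on day 1. The 2 arrays of each group had equal weights, such as 0.637 for both of control day 2, so this setting weighs groups and not single arrays. The lowest weights were those of day 1, at 0.532 for CLA and 0.513 for control. Genes above the median level gave 0 for control by day in limma (389 at an unadjusted p under 0.05), which leaves out the dim liver genes. The replicate block gave 36 for control by day, and the block within days gave 3037 on day 2, 3254 for the interaction and 3046 for late minus early. The replicate numbers were not treated as pairing, as the labels name no shared source and the deviations of the CLA and control arrays from their group means did not correlate over 0.1 across genes on every day. The correlations were 0.566, 0.490, 0.228, 0.114, 0.0978, 0.345 and 0.101 on the successive days, and between 0.344 and 0.623 among the 4 groups of days 1 and 2, so some structure tied to the numbers stays open, most of all on those 2 days. For the arrays of a day alone, the daily differences, array weights and both blocks the cause was not tested.

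With each of its 4 arrays left out in turn, and replicate 1 of control day 2 for every day, the counts ran from 2697 to 3590 on day 1, 343 to 2434 on day 2, 2687 to 4144 on day 3, 2846 to 4459 on day 4, 2095 to 3256 on day 7, 2432 to 3792 on day 10 and 2352 to 3837 on day 17. Over all days, with a day or 1 replicate number of every group left out, they ran from 5601 (without replicate 2 of every group) to 7897 (without day 1). With each array of the groups compared left out in turn they ran from 1461 to 2084 for the interaction, 1338 to 1910 for late minus early and 15 to 225 for control by day. The highest of these daily counts came without replicate 1 of control day 2, and the 343 and 225 without its partner. A group left with 1 array is assumed to vary like the others, and the cause was not tested. Weak signal limits calls near the lowest values, as dim probe sets were kept. Near the highest value, 14.18, changes may be understated, as the brightest probe set stood for each gene.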

Other observations

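The list tests given here were set beforehand, but the choice of lists and days to show here was not. Of 16 interferon response genes, 11 rose on day 4 in both counts, over all genes and adjusted over the list alone, among them Oas1a (2.84) and Oasl2 (2.19), sensors and effectors against viral RNA. The list median was 1.56 on that day (adjusted p = 1.93e-06, and adjusted p = 0.15 with an estimated correlation) and 0.40 on day 10, where 4 rose and 1 fell, or 5 and 1 adjusted over the list alone. Of 11 neutrophil genes 4 rose on day 1 in both counts, among them S100a9 (3.48) and the collagenase Mmp8 (1.17), with a median of 0.22 (adjusted p = 0.00899, and adjusted p = 0.11 with an estimated correlation). On this day the 3' minus 5' difference was high in both CLA arrays. Skeletal muscle genes had medians between -1.53 on day 7 and 0.77 on day 2, and 1 of 15 passed on day 4 in limma and 0 on the other 6 days, with 4 at an unadjusted p under 0.05 on day 7.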
